A study of Mus musculus with 6 samples.

How the data were processed

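RNA from 2 zones of the mouse lens, mature fiber cells and elongating fiber cells, was compared on 6 two-colour expression arrays. Per the labels, the cells were cut by laser capture from lens sections 5 µm thick, taken from a transgenic strain that expresses GFP, and every array held RNA of mature fibers in one channel and of elongating fibers in the other. Mature fibers were in channel 1 on 3 arrays and in channel 2 on the other 3. For the first array of each orientation the labels also give postnatal day 5, lenses pooled from littermates, at least 200 cells and about 40 slices. The labels do not say which arrays were made from separate animals or RNA extracts. P-values over the 6 arrays measure the spread between arrays, except those of the gene list test camera at its preset correlation. That spread may be technical and may make the p-values too small.

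The deposited values are log ratios of the 2 channels of each array, for 22575 probes with 0 missing values. The base of the logarithm, the channel used as numerator, the scanner software, the background correction and the normalization are not given in the sources used here. The median of the deposited ratios lay between -0.006 and 0.025 on the 6 arrays. Centring by the authors is therefore possible but not stated. The analysis had been planned on the log2 scale; with the base unknown, the values were kept in the deposited log units, and tests do not depend on the base. Folds are given only as readings under a stated base. No spot intensities, background levels or saturation flags were used here, so the precision of a single ratio is unknown, and the number of arrays limits the precision of the means.

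Before any test, correlations across genes were computed between arrays. By Pearson's r, all 9 combinations of arrays of opposite orientation lay below 0 (r from -0.63 to -0.05) and those of the same orientation above 0 (r from 0.13 to 0.34). By rank, 7 of the 9 lay below 0 (rho from -0.38 to 0.041), with lens249 above 0 against lens488 and lens455, and those of the same orientation lay above 0 (rho from 0.15 to 0.34). Genes are not independent replicates, so these carry no p-value. The ratios were accordingly read as running by channel, and the arrays with elongating fibers in channel 1 were turned in sign. After turning, the positive side means higher in mature fibers if channel 1 is the numerator, and lower in mature fibers if channel 2 is. This choice is open and exchanges both sides for every gene at once; which genes lie on the same side does not depend on it.

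Gene names came from the platform's probe annotation. Of all probes, 18218 had 1 symbol, 16 had several symbols and 4341 were unlisted and are unnamed here. Of those with 1 symbol, 18175 matched the RefSeq gene table of assembly GRCm38.p6 by gene ID, and 0 symbols needed updating; no coordinates were used. Rows with identical values on all 6 arrays were counted once, and 10 sets of at least 49 identical unlisted probes (1032 probes) were left out as probable control spots. Each array was centred on its median. Probes of one gene were averaged, which left 19624 features, of which 16504 were genes (1152 with several probes) and 3120 unnamed probes.

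The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, with a term for the difference between fiber populations and a term for the dye of each gene, Benjamini-Hochberg adjusted over all features at a threshold of 0.05. The dye term gave the test of the dye effect. The 25 gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists, with an estimated correlation and fry as alternatives. At the preset correlation camera sets a list's genes against the other genes, so its p-values measure spread between genes and not between arrays. With an estimated correlation its degrees of freedom come from the 6 arrays, so lists pass less easily. Errors are SDs over the 6 turned arrays. They include the dye effect of each gene, which the test fits as a term of its own, so they are not the spread behind the p-values. Groups, lists, tests and most alternatives were fixed before the data were examined. Genes were named by a rule fixed at the same time: the 12 largest log ratios on each side among genes past the threshold with the same sign on all arrays, up to 4 members with the lowest p of each list, and all measured crystallins. Other genes past the threshold were counted. Figures were drawn with matplotlib 3.10.9.

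The lists were crystallins, fiber cell membrane and cytoskeleton, lens transcription factors, lens epithelium markers, blood and vessel markers, retina and pigment cell markers, macrophage and leukocyte markers, lysosome, autophagy, proteasome, ubiquitin conjugation, apoptosis, cytosolic ribosome, mitochondrial respiratory chain, glycolysis, cell cycle, cyclin-dependent kinase inhibitors, chaperones, redox and glutathione, ion and water transport, FGF, TGF beta, BMP and Wnt signalling, cholesterol synthesis, translation factors, splicing and mRNA processing factors, and nuclear lamina, nuclear pore and histones.

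The scripts were tested on simulated data: residuals with each feature's own spread for the 19624 features, with 200 changed. With independent arrays, 60% of features changed by 0.5 log units were called, 90% at 1, 98% at 1.5 and 96% at 2, and 5 of 177 calls were false. When arrays in pairs shared 50% of their variance, 37 of 199 calls were false. Averaging such pairs to 3 values left 3 false calls of 119. The 50% was a chosen setting, not an estimate. In the real data limma estimated a correlation within pairs by title number of 0.16 with 2 pairs and 0.13 with 3 pairs. The false share in the real data is therefore not known from this simulation.

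Alternatives covered the dye term, centring and scaling, quantile normalization, the treatment of several probes, robust variance estimates, arrays in pairs by title number, each orientation alone, each array left out, a minimum fold, a test without moderation and the sign of all arrays. With 0 missing values, the planned filters on the number of arrays with a value removed no feature and were not run.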

Results

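The lens grows by laying down elongated fiber cells, which first lengthen and then mature toward its centre. Mature and elongating fibers of the mouse lens were compared on 6 two-colour arrays, 3 with mature fibers in channel 1 (replicates 1 to 3, titled lens249, lens487 and lens493) and 3 with elongating fibers in channel 1 (replicates 1 to 3, titled lens250, lens488 and lens455). Arrays are named below by these titles. Each gave a log ratio for 19624 features, of which 16504 were named genes. The question was which transcripts differ between the 2 stages of fiber maturation. Which stage is the higher one is open, because the numerator of the ratios is not stated. The positive side below is the side of Dnase2b and the negative side that of Cdh2; positive means higher in mature fibers if channel 1 is the numerator, and lower if channel 2 is. Values are in deposited log units of unknown base, as means ± SD of 6 arrays.

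The 2 fiber populations differed most in Stx11, a syntaxin of vesicle fusion, at 2.25 ± 0.60 (SD, n = 6). This is a 4.76-fold difference if the values are log2 and 179-fold if they are log10. On the same side lay Gadd45b, a stress-inducible growth arrest gene, at 1.99 ± 0.70, and Dnase2b, the lysosomal nuclease that degrades nuclear DNA in lens fibers, at 1.81 ± 0.30. On the opposite side Cdh2, which encodes the adhesion molecule N-cadherin, had the largest value, -1.78 ± 0.54, a 3.42-fold difference if log2 and 59.7-fold if log10. Ctsl, a lysosomal cysteine protease, lay with Cdh2 at -1.36 ± 0.20. All 5 genes had one sign on all 6 turned arrays, with limma adjusted p from 0.0034 to 0.016.

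Other genes on the positive side were Rnf180, a ubiquitin ligase (1.63 ± 0.53), Elavl4, a neuronal RNA-binding protein (1.57 ± 0.77), and Rubcn, a negative regulator of autophagy (1.53 ± 0.33). Plekhs1 (1.38 ± 0.55), the adhesion receptor Adgrl2 (1.37 ± 0.60), the klotho family member Lctl (1.28 ± 0.43) and Ralgds, an exchange factor for Ral GTPases (1.28 ± 0.59), followed. Ints6, of the Integrator complex, had 1.23 ± 0.34 and the secreted matrix protein Spon1 1.17 ± 0.26. On the negative side were Tom1l1 (-1.49 ± 0.33), the nuclear import receptor Ipo5 (-1.38 ± 0.13), the histone chaperone Nap1l1 (-1.37 ± 0.32), Zmym2 (-1.32 ± 0.40) and 1810014B01Rik (-1.25 ± 0.44). Rbm3, a cold-inducible RNA-binding protein (-1.23 ± 0.35), Svip (-1.21 ± 0.49), Ivns1abp (-1.20 ± 0.55), Idi1 of isoprenoid synthesis (-1.19 ± 0.33) and Rcn1, a calcium-binding protein of the endoplasmic reticulum (-1.18 ± 0.23), completed the 12 on this side. All 24 genes had one sign on all 6 arrays and passed the test, with adjusted p of at most 0.046.

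**Figure D1:**
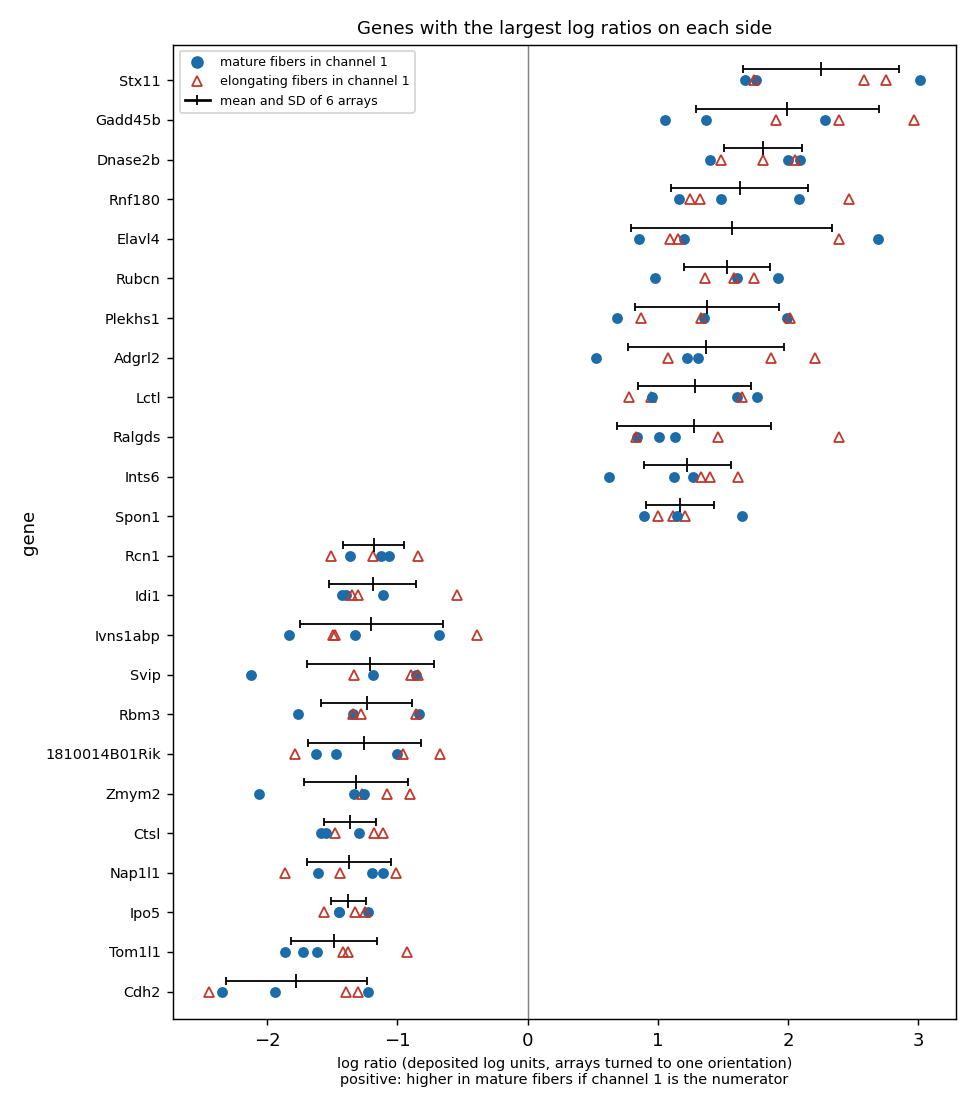
Log ratio (x axis, deposited log units, arrays turned to one orientation) of the 12 genes with the largest values on each side. Filled circles are arrays with mature fibers in channel 1, open triangles arrays with elongating fibers in channel 1, and bars the mean and SD of 6 arrays; every point lies on its gene's side of 0, from Stx11 at a mean of 2.25 to Cdh2 at -1.78.

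In all, 339 features passed an adjusted p of 0.05 in limma, 73 on the positive side (68 named genes) and 266, or 78.5%, on the negative side (244 named genes). At an unadjusted p under 0.05 there were 3183, against 981.2 by chance. Of the 339, 330 had one sign on all 6 arrays; over all features 9.17% did, against 3.125% by chance if the arrays are separate samples and up to 25% if arrays in pairs share material. The sizes of the 339 ranged from 0.337 to 2.25 with a median of 0.654. These counts treat each array as a replicate: if arrays with neighbouring title numbers (lens249 with lens250, lens487 with lens488) and the pair left over (lens455 with lens493) share RNA extracts, there are 3 replicates, and on 3 averaged pairs 0 features passed in limma, with 2395 at an unadjusted p under 0.05. Leaving out 1 array left 117 features without array lens249, 102 without lens250, 38 without lens487, 16 without lens488, 71 without lens493 and 84 without lens455, and each orientation alone gave 0, with 2609 and 2670 at an unadjusted p under 0.05 for mature and elongating fibers in channel 1.

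Genes of fiber cell structure lay on both sides. Dnase2b and Lctl were on the positive side, and Cdh2 and ezrin (Ezr, -1.04 ± 0.15, adjusted p = 0.0058), which links membrane to actin, on the negative side. Of the 30 measured genes of the fiber cell membrane and cytoskeleton list, 2 passed on the positive and 4 on the negative side, and 24 did not pass. Adjusted over the list alone, 3 and 10 passed. The list's mean was -0.12 ± 0.16 (camera adjusted p = 0.062), and without array lens455 it passed at -0.16 (adjusted p = 0.012; adjusted p = 0.31 with an estimated correlation), as it did without array lens493 at -0.14 (adjusted p = 0.017; adjusted p = 0.45 with an estimated correlation). Among 21 lens transcription factors only Meis2, a homeobox gene, passed (-1.06 ± 0.25, adjusted p = 0.0081), over all features and over the list alone. Pax6, a master regulator of eye development, had -0.59 ± 0.43 and did not pass (adjusted p = 0.13). That list's mean was -0.14 ± 0.10 (camera adjusted p = 0.17).

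Crystallins, the main structural proteins of the lens, did not pass the test as a group. Of 14 measured genes 1 passed, Crygn, at -0.62 ± 0.43 (adjusted p = 0.029), also over the list alone. Crygn was below 0 on 5 of 6 arrays, and its dye effect was 0.34 (limma adjusted p = 0.27). Its call held in 1 of the 6 fits without 1 array (limma adjusted p up to 0.10). Crygs had -0.34 ± 0.47, while Cryge (0.65 ± 1.21) and Cryaa (0.17 ± 0.86) were each at a value shared with other crystallins on 2 arrays, which leaves their size uncertain. The mean of the list was 0.0088 ± 0.55 (camera adjusted p = 0.68; adjusted p = 0.88 with an estimated correlation). That mean depended on array lens455: it had 0.92 there, and without it the list had -0.17 and passed (adjusted p = 0.0093; adjusted p = 0.31 with an estimated correlation), with several members at shared values on 3 of the other arrays. On these arrays crystallins carried one identical deposited value: -0.466 for 5 crystallins on array lens249, 0.45 for 10 on array lens250 and 0.196 for 8 on array lens493. Their log ratios on those arrays therefore carry no order. Without the 9 crystallins within 0.0015 of such values on at least 2 arrays, the 5 left had a mean of -0.25 ± 0.29 and did not pass (camera adjusted p = 0.067; adjusted p = 0.36 with an estimated correlation).

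**Figure D2:**
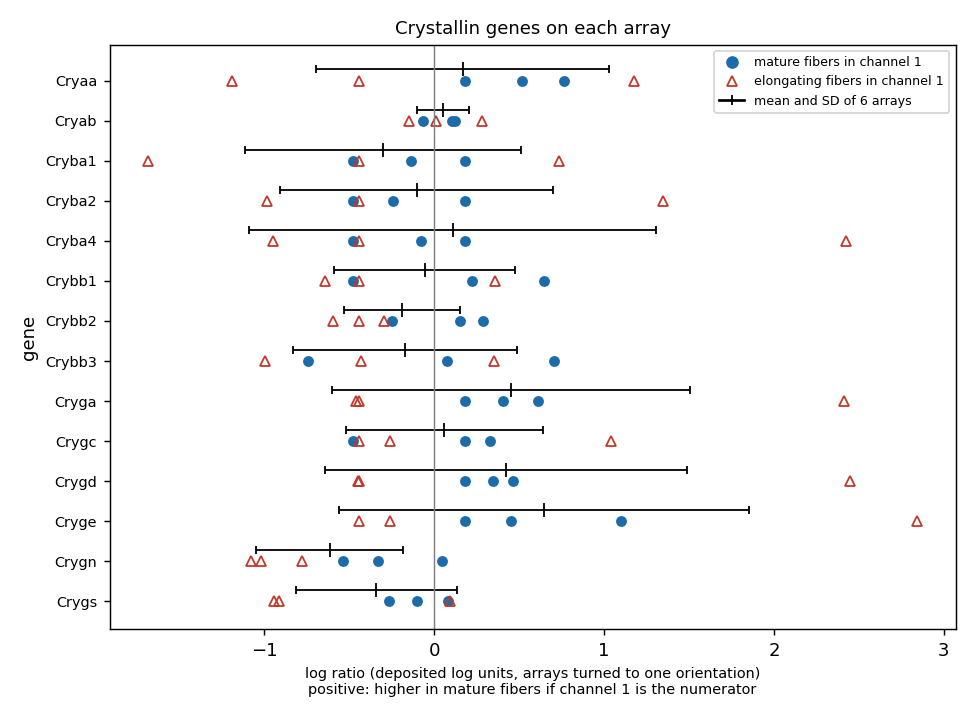
Log ratio (x axis, deposited log units, arrays turned to one orientation) of the 14 measured crystallin genes. Filled circles are arrays with mature fibers in channel 1, open triangles arrays with elongating fibers in channel 1, and bars the mean and SD of 6 arrays; the triangle of array lens455 reaches 2.84 for Cryge.

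Genes of RNA processing and protein synthesis lay mostly on the negative side, with Cdh2. Among splicing factors Srsf9 had -0.96 ± 0.31, Hnrnph2 -0.93 ± 0.39 and Prpf39 -0.88 ± 0.36. Among translation factors Eif5a2 had -0.87 ± 0.27 and Eif1ax, of start site selection, -0.71 ± 0.09, while Eif5b, which joins ribosomal subunits, lay on the other side at 0.78 ± 0.23. Ribosomal protein genes were led by Rpl13a (-0.77 ± 0.45), Rpl3 (-0.67 ± 0.27) and Rps4x (-0.63 ± 0.16). These genes passed the test, with adjusted p of at most 0.031.

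Of 63 measured splicing and mRNA processing factors 7 passed, all on the negative side, and 15 negative and 2 positive passed adjusted over the list alone. The list's mean was -0.19 ± 0.08 and below 0 on 6 of 6 arrays (camera adjusted p = 7.1e-06; adjusted p = 0.27 with an estimated correlation). Of 61 translation factors 4 passed on the negative and 1 on the positive side, and 9 and 1 over the list alone. Their mean was -0.17 ± 0.11, below 0 on 6 arrays (camera adjusted p = 1.1e-05; adjusted p = 0.27 with an estimated correlation). Of 71 cytosolic ribosome genes 5 passed, all negative, and 17 negative and 1 positive over the list alone. Their mean was -0.15 ± 0.10, below 0 on 6 arrays (camera adjusted p = 2.0e-05; adjusted p = 0.27 with an estimated correlation).

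The genes of the cholesterol synthesis, glycolysis and respiratory chain lists that passed the test lay on the same side, while 6 of 20, 7 of 22 and 27 of 86 measured members were above 0. The cholesterol synthesis genes Idi1, Hmgcs1 (-1.06 ± 0.41) and the sterol sensor partner Insig1 (-0.82 ± 0.35) passed, 3 of 20 measured, all negative, and 9 negative over the list alone. The list had the largest mean of the 25, -0.31 ± 0.11, below 0 on 6 arrays (camera adjusted p = 0.00028; adjusted p = 0.27 with an estimated correlation). In glycolysis, 4 of 22 genes passed, all negative: Pfkfb3, which makes an activator of phosphofructokinase (-1.13 ± 0.62), Eno3 (-0.96 ± 0.35), Pgk1 (-0.83 ± 0.38) and Aldoc (-0.66 ± 0.20), and 7 negative passed over the list alone. The glycolysis mean was -0.19 ± 0.03 (camera adjusted p = 0.0084; adjusted p = 0.27 with an estimated correlation).

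Of 86 respiratory chain genes 2 passed, Atp5a1 of ATP synthase (-0.69 ± 0.30) and Sdhd of succinate dehydrogenase (-0.43 ± 0.20), and 4 negative over the list alone. Their mean was -0.07 ± 0.07 (camera adjusted p = 0.034; adjusted p = 0.39 with an estimated correlation). Of 40 proteasome genes only the core subunit Psma4 passed (-0.55 ± 0.20), also over the list alone, and the list's mean was -0.11 ± 0.06 (camera adjusted p = 0.020; adjusted p = 0.30 with an estimated correlation). Both list calls were lost without array lens487, at adjusted p = 0.208 and 0.0703, and the respiratory chain call also without array lens250 (0.109) or lens455 (0.0661).

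**Figure D3:**
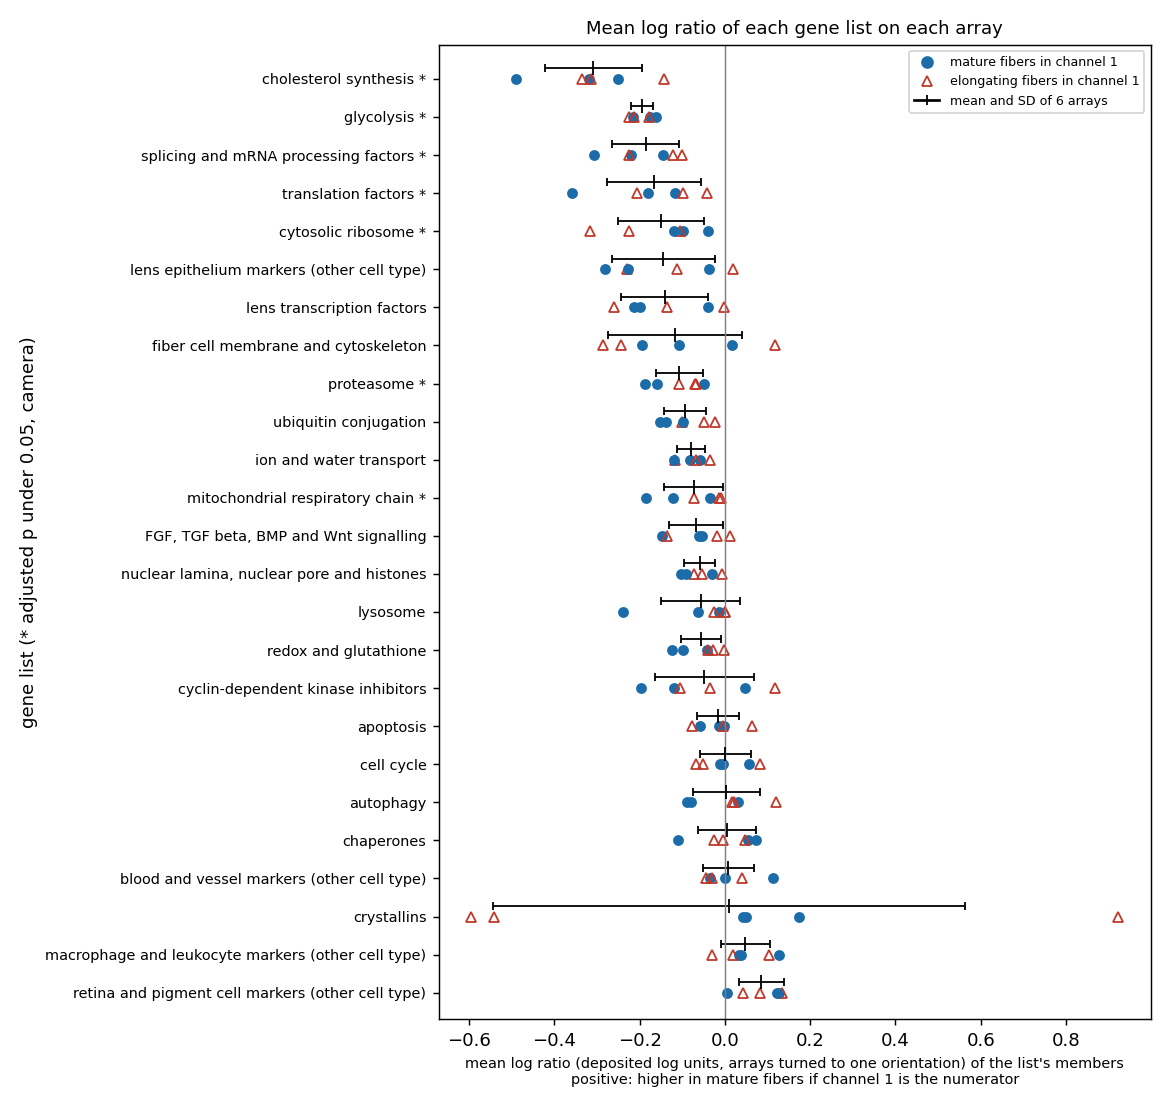
Mean log ratio of the members of each of 25 gene lists (x axis, deposited log units, arrays turned to one orientation) on each array. Filled circles are arrays with mature fibers in channel 1, open triangles arrays with elongating fibers in channel 1, bars the mean and SD of 6 arrays, and stars mark the 7 lists past the threshold by camera, which all lie below 0.

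Altogether 7 of 25 lists passed by camera at its preset correlation, all on the negative side. With an estimated correlation 0 passed (smallest adjusted p = 0.273). For glycolysis (-0.031) and cholesterol synthesis (0.0062) this correlation was below the preset 0.01, and for the others of the 7 it was 0.024 to 0.068. A higher correlation between genes therefore does not account for the loss of the glycolysis and cholesterol synthesis calls. The estimated setting also takes its degrees of freedom from the 6 arrays, which leave few, and the preset one takes them from the genes. For these lists no other difference between the settings is left. For the others of the 7, the parts of correlation and degrees of freedom were not told apart. By fry, which asks whether a list's genes move one way, 10 passed, including 6 of the 7. The respiratory chain did not pass by fry (adjusted p = 0.083). Lens transcription factors, ubiquitin conjugation, redox and glutathione, and ion and water transport passed by fry (adjusted p = 0.028 each) but not by camera.

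Lysosome, ubiquitin conjugation and chaperone genes passed the test on both sides. Of 40 lysosome genes Dnase2b and Atp6ap2, an accessory subunit of the proton pump (0.50 ± 0.37), passed on the positive side and Ctsl on the negative side, with 3 on each side over the list alone (mean -0.06 ± 0.09, camera adjusted p = 0.25). Of 34 autophagy genes Wipi2 passed (0.51 ± 0.37), with 3 positive and 2 negative over the list alone (mean 0.0039 ± 0.08, adjusted p = 0.79). In ubiquitin conjugation the cullin Cul4a (-1.12 ± 0.31), the deubiquitinase Usp9x (-1.01 ± 0.43) and Sumo2 (-0.83 ± 0.11) passed on the negative side and the proteasome-bound deubiquitinase Usp14 (0.51 ± 0.23) on the positive. That list counted 47 genes, with 5 negative and 4 positive over the list alone (mean -0.09 ± 0.05, adjusted p = 0.13). Of 40 chaperones 2 passed on the positive side, including Bag3, a co-chaperone of Hsp70 (1.09 ± 0.40), and the chaperonin subunit Cct8 (0.57 ± 0.24). There were 3 on the negative side, including its partners Cct6a (-0.52 ± 0.13) and Cct2 (-0.46 ± 0.21), and 5 on each side over the list alone (mean 0.0057 ± 0.07, adjusted p = 0.71). Of 37 redox genes Gsr, glutathione reductase, passed (-0.47 ± 0.14), with 4 negative and 3 positive over the list alone (mean -0.06 ± 0.05, adjusted p = 0.12). Hmox1, heme oxygenase, had 1.21 ± 0.64 and did not pass (adjusted p = 0.058).

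Cell cycle genes showed no difference past the threshold: of 42 measured, 0 passed in limma over all features or over the list alone, and the mean was 0.0012 ± 0.06 (camera adjusted p = 0.79). Mcm3 had the lowest p among them (0.39 ± 0.21, adjusted p = 0.081). Of 7 cyclin-dependent kinase inhibitors 0 passed over all features and 1, Cdkn1c, over the list alone (-0.61 ± 0.32, adjusted p over all features = 0.060; list mean -0.05 ± 0.12, adjusted p = 0.71). Of 42 apoptosis genes the mitochondrial protease Htra2 passed (-0.46 ± 0.08), with 3 negative and 2 positive over the list alone (mean -0.01 ± 0.05, adjusted p = 0.92). Of 60 signalling genes of the FGF, TGF beta, BMP and Wnt pathways 0 passed and 3 negative passed over the list alone (mean -0.07 ± 0.06, adjusted p = 0.66). Id1, a target of BMP signalling, had -1.46 ± 0.75 (adjusted p = 0.052). Of 30 ion and water transport genes Clic1 (-0.53 ± 0.18) and the channel kinase Trpm7 (-0.43 ± 0.23) passed, with 4 negative and 1 positive over the list alone (mean -0.08 ± 0.03, adjusted p = 0.25). Of 80 genes of the nuclear lamina, nuclear pore and histones, the transport factors Ranbp1 (-0.88 ± 0.34), Kpna1 (-0.71 ± 0.28) and Xpo1 (-0.64 ± 0.32) passed, and 4 negative over the list alone (mean -0.06 ± 0.04, adjusted p = 0.32). In the lists of crystallins, chaperones, cell cycle, autophagy and macrophage markers the mean was above and the median below 0; camera's direction was negative for the first 2.

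Of the markers of other cell types that a dissected zone could hold, 2 passed the test. Of 21 lens epithelium markers the basement membrane collagen Col4a1 passed (-0.95 ± 0.38, adjusted p = 0.030), on the side of the ribosomal and splicing genes. Adjusted over the list alone, 3 negative and 1 positive passed, and the mean was -0.14 ± 0.12 (camera adjusted p = 0.71). Of 14 macrophage and leukocyte markers Laptm5 passed (0.35 ± 0.21, adjusted p = 0.039), on the side of Dnase2b, with 2 positive over the list alone (mean 0.05 ± 0.06, adjusted p = 0.49). Of 16 blood and vessel markers 0 passed (mean 0.0075 ± 0.06, adjusted p = 0.88), and of 16 retina and pigment cell markers 0 passed (mean 0.09 ± 0.05, above 0 on 6 arrays, adjusted p = 0.12), over all features or over the list alone.

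The dye orientations were also compared. No feature showed a dye effect past the threshold in limma (0 of 19624, smallest adjusted p = 0.146). At an unadjusted p under 0.05 limma gave 2476, against 981.2 by chance, so dye effects are not shown to be absent. Across features, which are not independent replicates, the mean turned ratios of the 2 orientations correlated with r = 0.40 and rho = 0.19, and 52.0% had the same sign in both. Among the 339 features past the threshold, which were selected for that, 99.4% had the same sign.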

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

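The tests of the shared crystallin values were chosen after those values were seen. Among 127 named genes, 8 had 1 of 6 turned ratios far from the other 5; chance alone gives about 1 in 20 such genes, or 6.35. On array lens455, Crygd had 2.45 where the other arrays lay between -0.449 and 0.461, Cryba4 had 2.42 against -0.949 to 0.182, and Cryga 2.41 against -0.461 to 0.611. Also on array lens455, Idi1 had -0.543 against -1.42 to -1.11, and Rps4x -0.956 against -0.615 to -0.523. On array lens493, Cul4a had -1.74 against -1.06 to -0.912 and Zmym2 -2.06 against -1.33 to -0.899. On array lens250, Cdkn2a had 0.78 against -0.113 to 0.197.

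Of the crystallins that stood apart on array lens455, Cryba4 had the value shared by other crystallins on each of the arrays lens249, lens250 and lens493, and Crygd and Cryga on lens250 and lens493. In all, 31 features lay within 0.0015 of these values on at least 2 of the 3 arrays, and 24 were equal to them. Besides 9 of 14 crystallin probes these included Eef1a1, Ppia, Tuba1a and Gsn, and also Insl5, A730081D07Rik and Dkk3. How abundant these transcripts are was not measured here. Repeated or merged probes given 1 common value were argued against, since the same 9 crystallins had 9 distinct values on each of the arrays lens487, lens488 and lens455. A scanner ceiling in both channels for very abundant transcripts may explain the shared values: 6 of 76 ribosomal protein probes (7.89%) were within 0.0015 of them, against 13 of 17696 other named probes (0.0735%; one-sided Fisher exact p = 1.3e-10). Counting equal values only, 3 ribosomal protein probes (3.95%) and 9 others (0.0509%) were at them (one-sided Fisher exact p = 1.6e-05). Scanner signals were not used here, so the ceiling was not seen directly, and no biological explanation was tested.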

How the results depend on the processing

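Alternatives that left out a pair of arrays, blocked on 3 pairs, removed features within 0.0015 of the shared crystallin values or joined a left-out array, pair or set of features with an estimated correlation were chosen after seeing the data. The 339 features (73 positive, 266 negative) stayed within 1.5 times with no dye term, without centring, with scaling, quantile normalization, single probes, robust variances and pairs as a random block (282 to 443; 282 of the 339 were among the calls with 3 pairs as a block). On 3 averaged pairs the count was 0, as it was with either orientation alone and without the pair lens249 and lens250 or lens487 and lens488, on each side; at an unadjusted p under 0.05 limma gave 2395, 2609, 2670, 3096 and 1877. The cause was not tested. On simulated data with independent arrays, 3 averaged pairs gave calls for 4% of changes of 0.5 log units and 76% of 1. The rates were 90% for 1.5 and 86% for 2, and with shared variance 0%, 64%, 80% and 88%. The median size of the 339 was 0.654, and 48 of them had a size of at least 1 log unit. At such sizes the simulated rates were 64% to 90%. In the real data 0 of these 48 passed on 3 averaged pairs (smallest limma adjusted p over all features = 0.247). The sizes of these 48 are estimates from the arrays that selected them and may be too large. The simulated rates are for true sizes, so they do not exclude small size as the reason for the loss. Without the pair lens455 and lens493 the count of features was 69 (17 positive, 52 negative). Leaving out 1 array gave 16 to 117 (2 to 33 positive, 14 to 96 negative). A minimum of 2-fold gave 48 (17 and 31) if the values are log2 and 339 if log10. An ordinary one-sample test, without moderation and without a dye term, gave 19 (3 and 16). The moderated fit without a dye term gave 443. The cause was not tested. With every array turned the other way, 266 were positive and 73 negative by construction.

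Of 127 named genes, 0 of the 67 that passed changed sign under the alternatives computed for single genes, which do not include turning every array; 9 passed in all 6 fits without 1 array (Ctsl, Dnase2b, Ezr, Ipo5, Meis2, Nap1l1, Stx11, Sumo2 and Tom1l1), 26 passed in none of them (Atp5a1, Atp6ap2, Cct2, Cct6a, Cct8, Clic1, Eef1e1, Eif5a2, Elavl4, Gsr, Hmgcs1, Hnrnph2, Htra2, Ivns1abp, Laptm5, Pfkfb3, Plekhs1, Prpf4b, Psma4, Rpl24, Rpl3, Sdhd, Trpm7, Usp14, Wipi2 and Xpo1), and 0 passed on 3 averaged pairs. The count of features with a dye effect past the threshold stayed at 0, and the agreement of orientations was 0.41 with quantile normalization. The 7 lists fell to 0 with an estimated correlation, also with any array, any pair or the features at shared values left out. That setting has few degrees of freedom, and leaving out arrays lowers them. These losses thus do not show that correlation between genes removes the shifts. The count stayed between 5 and 10 otherwise, with 7 on 3 averaged pairs, where 0 features passed. Camera's p-values at the preset correlation do not measure spread between arrays, so its counts do not show that the shifts repeat over arrays. Without the features at shared values the crystallin mean was -0.25, short of the threshold (adjusted p = 0.067). Over all 14 crystallins the mean was -0.17 to 0.13 with 1 array left out; it turned to -0.17 without array lens455 and to -0.26 without the pair lens455 and lens493, past the threshold both times at the preset correlation but not with an estimated one (adjusted p = 0.31 and 0.34); the cause was not tested. Array signal over background was not used here.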

Other observations

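The tests of shared RNA extracts, of the side of mature fibers and of other groupings of arrays for gene counts were chosen after the results were seen; the count of lists in other groupings was set before. Some list members past the threshold fall outside the naming rule and were chosen after their values were seen. On the negative side these were P4hb, a disulfide isomerase of the endoplasmic reticulum (-0.75), the tubulin Tubb5 (-0.59), Basp1 (-0.52), Eif3e (-0.48), Rpl15 (-0.38), Hnrnpdl (-0.79), Srsf2 (-0.54) and Hnrnpa1 (-0.34). Vim, the intermediate filament vimentin, had -0.81 without passing (adjusted p = 0.07).

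Of the repeated unlisted probe sets left out, one of 123 copies had -3.95 on array lens455 and -2.58 on array lens493, the same sign in both orientations before turning. A second of 123 copies had -3.73 and -1.56 there.

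The count of differing genes depended on whether an array or a pair of arrays is the replicate. Arrays with neighbouring title numbers, and the 2 left over, may share RNA extracts, and the values did not settle it. Correlations of the turned ratios across genes, which are not independent replicates, were 0.164 for lens249 with lens250, 0.630 for lens487 with lens488 and 0.473 for lens493 with lens455, against 0.053 to 0.168 among the 6 other combinations of opposite orientation. After the fitted terms were taken out they were 0.188, 0.575 and 0.372, against -0.361 to -0.053, so lens249 with lens250 stood apart there and not before; the fit makes the residuals of each orientation sum to 0, so values above 0 within pairs force values below 0 elsewhere. There are 6 ways to pair the arrays, and the title numbers gave the highest mean before these terms were taken out (0.42, next 0.28), a rank chance gives 1 time in 6; a shared slide or day and separate material stay open too.

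Chance as the source of the counts was tested with other groupings of the arrays. For the fit with a dye term, 1 of the 10 splits of 3 against 3 arrays, the real one, gave as many as 339 features, and the highest other gave 0; 10 splits are too few for a share under 0.05. For the lists, 1 of 10 splits gave as many as 7 and the highest other 5, with the same limit. Among the other splits only that of lens249, lens250 and lens487 against the rest gave 0 lists. The remaining ones gave 1 to 5 lists, though each gave 0 features. Camera at the preset correlation thus passed lists in most other groupings too. Without the dye term, 1 of 32 sign patterns, the real one, gave as many as 443 features, and the highest other gave 0. That share (0.0312) is the smallest that 32 patterns can give, and holds only if the arrays are separate samples. The turning of the arrays was itself chosen from the correlations between them, so this share does not exclude chance. If the 3 pairs are the replicates there are 4 patterns, too few for a share under 0.05.

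A hypothesis is that channel 1 is the numerator, so that the positive side, with Dnase2b, is higher in mature fibers and the negative side, with N-cadherin, in elongating fibers. The prediction tested was that cell cycle genes and lens epithelium markers lie on the negative side. Neither list decided between the channels: camera gave an adjusted p = 0.792 for the cell cycle and an adjusted p = 0.709 for the epithelium markers. Both populations are fiber cells, so neither list need differ between them even if the hypothesis holds. These lists could thus not settle the direction of the differences, which stays open.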
